A study of Mus musculus with 4 samples.

How the data were processed

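RNA from sorted basal epidermal cells of 2 WT and 2 Ezh2cKO samples at embryonic day 16 was biotin-labelled and hybridised to Affymetrix mouse arrays, per the labels. The deposited values are MAS5 signal intensities, 1 per probe set and array on a linear scale, per the submitters' processing notes, which name MAS5 without a version. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal and scales each array to a common trimmed mean. The mean after trimming 2% at each end was 500.0 on each of the 4 arrays, so the authors' scaling was kept. The design text names the chip in more than 1 way, and the 45101 probe sets of the table were named through the platform annotation given for it. Detection calls were not used here, so whether a dim probe set was above background is not known, and MAS5 gives noisy values at the low end.

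Each array was mapped to its group and replicate number from its sample title. After 64 control probe sets were left out, 45037 remained. Of these, 34945 had 1 gene symbol, 932 had several and 9160 were not listed with a gene, and genes were named only from probe sets with 1 symbol. Symbols were updated through the gene identifier, with 34741 matched to the mouse RefSeq gene table (assembly GRCm38.p6), which was used only for names and for which genes neighbour each other. Values were transformed as log2(signal + 16). Probe sets were kept if their mean lay in the upper 60% (a mean signal of at least 73.2), which left 27022 probe sets, 23069 of them with 1 gene, for 12703 genes. A gene was represented by its kept probe set with the highest mean. Of 165 list genes with several kept probe sets, 65 had probe sets whose log2 differences had opposite signs.

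Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, no block, 2 residual degrees of freedom per probe set before moderation), with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. As a measure of size that uses no variance, probe sets at least 2-fold apart in all 4 pairs of an Ezh2cKO and a WT array were counted, with the 2 other splits of the 4 arrays beside them. A gene was called separated when both Ezh2cKO values lay on the same side of both WT values. Gene lists were tested with camera at an inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, which asks whether a list's genes move one way on balance, each adjusted over 28 lists. An estimated correlation rests here on 2 residual degrees of freedom, which also hold the difference between the array numbers. Single genes of a list were also adjusted over the list alone.

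The 28 lists covered Polycomb repressive complexes 1 and 2, basal, early spinous and late differentiation genes, S100 genes, barrier lipids, hair follicle placode and bud, proliferation, cyclin-dependent kinase inhibitors, Hox clusters, developmental regulators, AP-1, imprinted genes, interferon response, cholesterol synthesis, stress and dissociation, and markers of melanocytes, Merkel cells, periderm, dermal fibroblasts, endothelium, immune cells, skeletal muscle, erythroid cells, Schwann cells and nerve, adipocytes and embryo sex. The lists, the design, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were Ezh2, then per direction the 10 genes with the largest fold among called probe sets whose arrays were separated, filled up with genes that had an unadjusted p under 0.01 and were 2-fold apart in all array pairs, leaving out the sex list and probe sets without a single symbol, then up to 4 members per list with the largest moderated t. Since 0 probe sets were called, the second part held 6 genes higher and 1 lower by their brightest kept probe set, all taken by the fill-up. Values are printed for part of the list members that the rule takes. Genes outside the rule are said to have been named after their values were seen.

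The alternatives were pseudocounts of 1 and 64, no filter and the upper 40%, quantile normalization, scaling to a common median, the replicate number as a block, no intensity trend, an adjusted p of 0.1, a 1.5-fold size rule, the mean of a gene's probe sets, and leaving out each array in turn, where the lone array of a group is assumed to vary like the others. The median log2 difference over all kept probe sets was 0.0037. The fit was tested on simulated data of 27022 probe sets with 200 changed. With the spread between array numbers left out, the fit without a block recovered 51.5% of 2-fold, 99% of 4-fold and 100% of 8-fold changes for Ezh2cKO against WT, and with it simulated it recovered 0%, 0% and 49.5%. A simulated list of 28 genes shifted by log2 0.5 was found by camera, with p = 0.00514 at the estimated correlation, and of 100 unchanged lists 2 had an unadjusted camera p under 0.05 and 0 an adjusted one. The simulated lists held genes drawn at random with independent noise, while the estimated correlation of the real lists reached 0.86 (endothelial). The simulation thus does not show how often camera calls an unchanged list of correlated genes. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.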

Results

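Gene expression was measured in basal cells, the layer of the epidermis that holds its progenitors, sorted by flow cytometry from mouse skin at embryonic day 16. Embryos with a conditional knockout of Ezh2 (Ezh2cKO) were compared with wild-type (WT) embryos, in mice of mixed C57 and CD1 background. Ezh2 is the catalytic subunit of Polycomb repressive complex 2, which places a silencing methyl mark on histone H3, and the comparison asked which genes depend on that silencing in epidermal progenitors. There were 4 Affymetrix expression arrays, 2 per genotype, numbered replicate 1 and 2 in each. The median signal over all non-control probe sets was 91.6 in WT replicate 1, 87.4 in Ezh2cKO replicate 1, 137 in WT replicate 2 and 148 in Ezh2cKO replicate 2. Of 45037 non-control probe sets, 27022 passed the intensity filter and were tested. The labels do not state that the replicates came from separate animals. Xist signal was 86.9 in Ezh2cKO replicate 1 and 11333 in Ezh2cKO replicate 2, so these were not repeats of the same sample. For the WT arrays this is not known. The p-values measure only the spread between these samples, which may be technical in part or, in WT, wholly. The number of arrays limits the precision. Far more probe sets differed 2-fold between the arrays numbered 1 and those numbered 2 (1902) than between the genotypes (14). Of the 1902, 1844 were lower and 58 higher in the arrays numbered 1. Because the numbers differed this much, the difference between genotypes is also given within each number, from 1 array per genotype. Unless another error is named, signals are mean ± SD with n = 2, and fold changes were computed on the log2(signal + 16) scale, which understates the change of dim genes. A fit with 1 array left out leaves 1 genotype with a lone array. Its p-values measure no spread within that genotype and show no replicated difference between genotypes.

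Ezh2, the targeted gene, had a mean signal of 3469 ± 189 in WT and 984 ± 458 in Ezh2cKO (log2 difference -1.88, SE 0.34, 95% confidence interval -2.72 to -1.03). Both Ezh2cKO arrays lay below both WT arrays, at 661 and 1308 against 3336 and 3603. Within number 1 the Ezh2cKO signal was 0.202 times that of WT, and within number 2 it was 0.366 times. This was the only probe set kept for Ezh2, and the labels do not say which exons were deleted, so whether it lies in the deleted part is not known here. In limma the adjusted p was 0.999979 over all 27022 probe sets and 0.0212 adjusted over the list alone, the list being 11 members of Polycomb repressive complex 2. With 1 array left out, the adjusted p over all probe sets was 0.0432 without WT replicate 1, 0.00290 without WT replicate 2, 0.00122 without Ezh2cKO replicate 2 and 0.999995 without Ezh2cKO replicate 1.

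Genes of the granular and cornified layers, which basal cells normally keep low until they leave the basal layer, had higher signal in Ezh2cKO. Of the 28 measured members of the late differentiation list, 16 were higher in both Ezh2cKO arrays than in both WT arrays and 0 were lower in both. That is 57.1% of the list, while 8.53% of all 12703 genes were separated upwards, and unrelated arrays would give 16.7%. The median log2 difference of the list was 1.10 within number 1 and 0.58 within number 2. Flg, which encodes the keratin-bundling protein filaggrin, had a signal of 26.6 ± 4.0 in WT and 177 ± 10.4 in Ezh2cKO (log2 2.18, SE 0.51), 4.65-fold higher within number 1 and 4.40-fold higher within number 2. Its WT signals lay under the filter's level of 73.2 and no background level was used, so the size of its difference is uncertain, with log2 1.41 at a pseudocount of 64 and 2.69 at a pseudocount of 1. Lor, encoding the cornified envelope protein loricrin, had 2126 ± 527 in WT and 4526 ± 1559 in Ezh2cKO (log2 1.06, SE 0.30), with folds of 3.19 and 1.37. Its 3 probe sets gave log2 differences between 0.29 and 1.13.

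The Lce1 genes, which encode small structural proteins of the late cornified envelope and lie side by side in the epidermal differentiation complex, were prominent in the list, with Lce1c showing its largest difference. All 9 measured Lce1 genes were higher in Ezh2cKO within both numbers, by log2 1.28 to 2.95, with a median of 5.58-fold within number 1 and 2.81-fold within number 2. Lce1c had a signal of 55.3 ± 19.7 in WT and 638 ± 522 in Ezh2cKO (log2 2.95, SE 0.66), 12-fold higher within number 1 and 4.96-fold within number 2. Its WT signals lay under the filter's level of 73.2, so these folds are uncertain, with log2 2.33 at a pseudocount of 64 and 3.26 at a pseudocount of 1. Lce1a2 had 264 ± 11 and 1096 ± 698 (log2 1.83, SE 0.47), with folds of 5.58 and 2.27. Without Ezh2cKO replicate 1 the log2 difference was 2.02 for Lce1c and 1.14 for Lce1a2, and without Ezh2cKO replicate 2 it was 3.87 and 2.52. Crct1, a neighbouring cysteine-rich gene named after its values were seen, had 114 ± 12.2 in WT and 575 ± 464 in Ezh2cKO. For 5 of the 9 Lce1 genes the probe set was of a design type that can detect near-identical paralogs, so the values of single Lce1 genes are uncertain. The measured members of the Lce3 family, Lce3b and Lce3f, also named after their values were seen, were not separated between the genotypes. Outside the Lce genes, 7 of 17 list members (41.2%) were higher in both Ezh2cKO arrays.

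The late list passed camera at its preset inter-gene correlation (mean log2 difference 0.99, adjusted p = 3.24e-27), with adjusted p = 0.502 with an estimated correlation. No single member passed limma's adjusted threshold, over all probe sets or adjusted over the list alone (0 of 28, lowest adjusted p 0.0708). With 1 array left out, the adjusted p over all probe sets passed for Lce1c without WT replicate 1 (0.0432), WT replicate 2 (5.64e-04) or Ezh2cKO replicate 2 (0.00591). It passed for Lce1a2 without WT replicate 2 (0.0270) or Ezh2cKO replicate 2 (0.00461), for Lor without WT replicate 2 (0.0468), and without Ezh2cKO replicate 2 for Crct1 (0.0101) and Lce1d (0.0292). Without Ezh2cKO replicate 1 none of the 5 passed, and the log2 difference was 0.71 for Lor, 1.02 for Crct1 and 1.27 for Lce1d. Without Ezh2cKO replicate 1 the list mean was 0.73 and camera's adjusted p 7.95e-14. The split that crossed genotype and number, Ezh2cKO replicate 1 and WT replicate 2 against the rest, gave the list a mean of 0.30 and camera's adjusted p of 0.0184. Other measured features differed alongside: Xist had a signal of 86.9 in Ezh2cKO replicate 1 and between 8669 and 11333 in the other arrays, the endothelial list had a median of -0.87 within number 1, and the stress and dissociation list had medians of 0.39 and 0.41 within numbers 1 and 2.

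**Figure D1:**
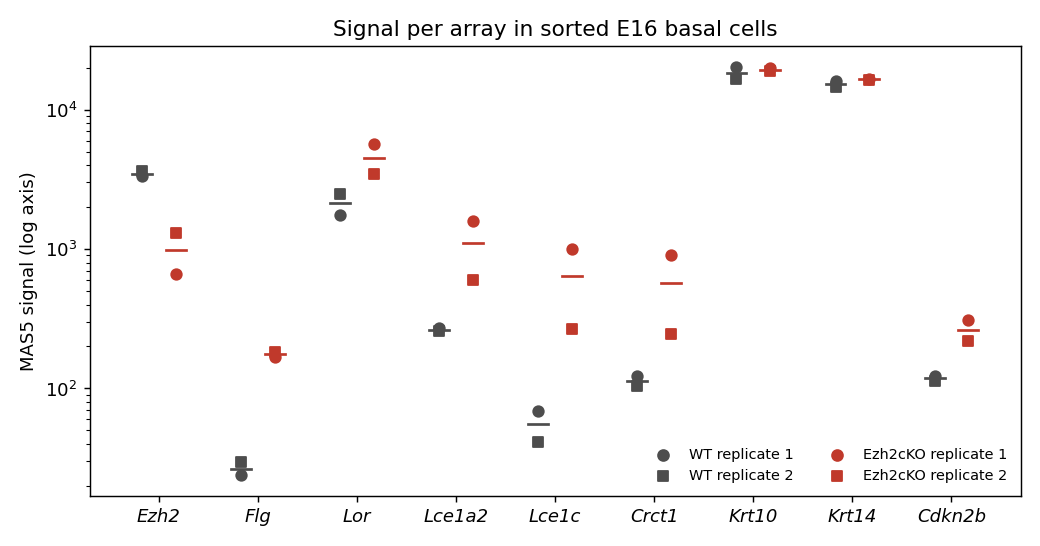
MAS5 signal (log axis) of 9 genes on each of the 4 arrays, with circles for replicate 1, squares for replicate 2, grey for WT, red for Ezh2cKO and a line at each group's mean (n = 2). Ezh2 lies lower and Flg, Lor, Lce1a2, Lce1c, Crct1 and Cdkn2b lie higher on both Ezh2cKO arrays than on both WT arrays, while Krt10 overlaps between the genotypes and Krt14 lies at 15241 and 16500.0 on average.

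Krt14, a keratin of basal cells, had 15241 ± 1047 in WT and 16500.0 ± 129.5 in Ezh2cKO (log2 0.12, SE 0.12). Itga6, the hemidesmosome integrin of basal cells, had 11273 ± 897 and 7869 ± 2181 (log2 -0.54, -0.91 within number 1 and -0.18 within number 2). Of 15 basal genes, 3 were higher and 2 lower in both Ezh2cKO arrays, and the list did not pass camera (adjusted p = 0.908). Krt1, a keratin of spinous cells, had 11727 ± 1718 in WT and 13036 ± 1139 in Ezh2cKO. Krt10, its partner keratin, named after its values were seen, had 18413 ± 2634 and 19315 ± 670.2. Krt14, Krt1 and Krt10 lay high on arrays whose largest signals were 21906 to 24300. Differences may be compressed there, so small ones do not show equal levels. Ivl, the envelope protein involucrin, had 89.3 ± 54.7 and 164 ± 0.246 (log2 0.88, SE 0.51). Dsc1, a desmosomal cadherin, had 469 ± 34.1 and 618 ± 6.90. Of 14 spinous genes, 3 were higher in both Ezh2cKO arrays and 0 were lower, with list medians of 0.07 and 0.18 within numbers 1 and 2. The spinous list passed camera (mean 0.17, adjusted p = 0.0215), with adjusted p = 0.593 with an estimated correlation. Its call was lost without WT replicate 2 (adjusted p 0.449), Ezh2cKO replicate 1 (0.333) or Ezh2cKO replicate 2 (0.164), without the filter (0.0756) and in the upper 40% of probe sets (mean 0.10, adjusted p 0.0808). Neither the epidermal barrier lipid list (18 genes, 2 higher and 2 lower in both arrays, adjusted p = 0.292) nor the S100 family (11 genes, 2 higher and 1 lower, adjusted p = 0.455) passed camera.

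Among Polycomb genes, Bmi1, a core subunit of Polycomb repressive complex 1, had 1766 ± 187 in WT and 3293 ± 466 in Ezh2cKO (log2 0.89, SE 0.19). It was 1.90-fold higher within number 1 and 1.81-fold within number 2, with limma's adjusted p of 0.0665 over its list alone. Of the 16 members of complex 1, 2 were higher and 1 was lower in both Ezh2cKO arrays. Rnf2, a ubiquitin ligase of the complex, had log2 differences of 0.63 and -0.03 within the numbers. The complex 1 list passed camera (mean 0.14, adjusted p = 0.0297), with adjusted p = 0.593 with an estimated correlation, and its medians were 0.11 and -0.01 within the numbers. This call was lost without WT replicate 2 (adjusted p 0.251) or Ezh2cKO replicate 1 (mean 0.07, 0.623), without the filter (0.075), without the intensity trend (0.0589) and with the mean of each gene's probe sets (mean 0.09, 0.209). In complex 2, apart from Ezh2, its paralog Ezh1 had 486 ± 24.6 in WT and 382 ± 7.70 in Ezh2cKO, Suz12 had 1949.9 ± 66 and 1840.5 ± 108, and Jarid2 had 1612 ± 251 and 1793 ± 25.2. The 2 kept probe sets of Ezh1 had log2 differences of -0.33 and 0.003, and the 5 of Suz12 lay between -0.27 and 0.02. The complex 2 list, Ezh2 included, did not pass camera (2 of 11 lower in both arrays, 0 higher, adjusted p = 0.126), but did without WT replicate 1 (mean -0.25, adjusted p 0.0118).

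Hox genes encode body-axis regulators that Polycomb silences in many tissues, and none of the 23 measured passed limma's adjusted threshold over all probe sets or adjusted over the list alone. The array held 33 Hox genes, and those below the intensity filter were not tested. Of the 23, 5 were higher and 3 lower in both Ezh2cKO arrays, where 8.53% and 8.40% of all genes were and unrelated arrays would give 16.7% in each direction. At an unadjusted limma p under 0.05, 5 of the 23 were higher and 1 lower by their brightest probe sets. Of all 27022 probe sets, 94 were higher and 16 lower at that level. Camera asks for a shift one way, so it can miss a list with members moving both ways. The list did not pass camera (mean 0.14, median -0.02, adjusted p = 0.292). Among those with the largest moderated t, Hoxa7 had 247 ± 89 in WT and 539 ± 72.6 in Ezh2cKO (log2 1.11, SE 0.32), Hoxc9 had 65.8 ± 35.9 and 200.2 ± 36.9 (log2 1.47, SE 0.49), Hoxc8 had 1047 ± 257 and 1695 ± 211, and Hoxd8 had 784 ± 120.1 and 1239 ± 82.2. The array held 99 developmental regulators of other lineages, such as Pax, Sox and Gata genes, of which 41 passed the intensity filter. Of these 41, 3 were higher and 5 lower in both Ezh2cKO arrays (camera adjusted p = 0.908). The dimmer regulators were not tested, so the result does not cover them. The list's mean was 0.29 without Ezh2cKO replicate 1 and -0.28 without Ezh2cKO replicate 2.

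Cdkn2b, the cell cycle inhibitor p15, had 118 ± 8.10 in WT and 263 ± 62.9 in Ezh2cKO (log2 1.04, SE 0.34), 2.32-fold higher within number 1 and 1.83-fold within number 2. Its neighbour Cdkn2a lay below the filter, with signals of 23.1 and 19.5 on the WT arrays and 26.3 and 48.4 on the Ezh2cKO arrays. Cdkn1b, the inhibitor p27, had 1403 ± 25.7 in WT and 1181 ± 34 in Ezh2cKO. Of 7 measured cyclin-dependent kinase inhibitors, 1 was higher and 1 lower in both arrays (camera adjusted p = 0.246). Of 28 proliferation genes, 2 were higher and 1 lower (camera adjusted p = 0.908). The proliferation list's mean was -0.16 without Ezh2cKO replicate 1 and 0.17 without Ezh2cKO replicate 2. Among 19 genes of hair follicle placodes and buds, 2 were higher and 1 lower. Nfatc1, a transcription factor of follicle stem cells, had 605 ± 56 in WT and 899.9 ± 48.5 in Ezh2cKO (log2 0.56, SE 0.20). Its 5 kept probe sets gave log2 differences between 0.09 and 0.56. The follicle list did not pass camera (adjusted p = 0.163), and its mean was 0.41 without WT replicate 1 (adjusted p 7.90e-08), 0.46 without Ezh2cKO replicate 2 (1.15e-06) and -0.22 without Ezh2cKO replicate 1 (0.0154).

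Genes of cholesterol synthesis had slightly higher signal in Ezh2cKO. Of 18 measured members, 7 were higher in both Ezh2cKO arrays and 0 lower, with medians of 0.33 and 0.14 within numbers 1 and 2. Msmo1, a sterol methyl oxidase, had 1366 ± 87.8 in WT and 1863 ± 279 in Ezh2cKO, Idi1, an isomerase of the pathway, had 1939 ± 153 and 2768 ± 792, and Cyp51, a sterol demethylase, had 811 ± 30.8 and 1050.4 ± 3.29. The list passed camera (mean 0.23, adjusted p = 1.28e-06), with adjusted p = 0.619 with an estimated correlation. The call was lost without WT replicate 2 (mean 0.17, adjusted p 0.067) or Ezh2cKO replicate 1 (mean 0.07, adjusted p 0.567), and the mean was 0.38 without Ezh2cKO replicate 2.

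Among immediate early and heat shock genes, which also respond to the dissociation of a tissue, 13 of 19 list members were higher in Ezh2cKO within both numbers and 1 was lower. Hspa1a, an inducible chaperone, had 1191 ± 395 in WT and 1913 ± 29.6 in Ezh2cKO (log2 0.72, SE 0.27), Dusp1, a phosphatase induced by stress, had 2554 ± 1742 and 4465 ± 1379, and Ier2 had 5251 ± 1324 and 7947 ± 2135. The list's heat shock genes other than Hspa1a lay between log2 -0.07 and 0.13 by their brightest probe sets, and between -0.39 and 0.69 over all kept ones. Of the 19 genes, 2 were higher in both Ezh2cKO arrays than in both WT arrays, near the 8.53% of all genes, and 0 were lower, with medians of 0.39 and 0.41 within the numbers. The same list was higher in WT replicate 2 than in WT replicate 1 by a median log2 of 0.74. Of 10 AP-1 transcription factor genes, 2 were higher and 0 lower (medians 0.58 and 0.39), and Jun had 6083 ± 2909 in WT and 9534 ± 4753 in Ezh2cKO, 1.53-fold and 1.58-fold within the numbers. The stress list passed camera (mean 0.41, adjusted p = 7.13e-07), as did the AP-1 list (mean 0.47, adjusted p = 0.0297), with adjusted p = 0.593 and 0.619 with an estimated correlation. The stress call was lost without WT replicate 1 (mean 0.08, adjusted p 0.236) or Ezh2cKO replicate 2 (0.06, 0.491), and its mean was 0.75 without WT replicate 2 and 0.77 without Ezh2cKO replicate 1. The AP-1 mean was -0.24 without WT replicate 1 (adjusted p 0.0132), -0.20 without Ezh2cKO replicate 2 (0.217), 1.18 without WT replicate 2 and 1.14 without Ezh2cKO replicate 1. Its call was lost without the filter (0.314) and without the intensity trend (0.124). Without WT replicate 2, Jun (log2 1.15, adjusted p 0.0402) and Dusp1 (1.71, 7.99e-04) passed limma's adjusted threshold. Without WT replicate 1 the log2 difference was 0.13 for Jun and 0.20 for Dusp1, and without Ezh2cKO replicate 2 that of Jun was 0.11.

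Markers of blood vessels had lower signal in Ezh2cKO within number 1 and not within number 2, and markers of fat differed between both WT arrays as well as between the genotypes. Car3, a carbonic anhydrase abundant in fat, had 7438 in WT replicate 1 and 220.4 in Ezh2cKO replicate 1, against 1891 and 979.6 in the arrays numbered 2 (log2 -2.96, SE 0.88). Adipoq, encoding the fat hormone adiponectin, was 0.0465 times its WT level within number 1 and 0.696 times within number 2, and Fabp4, a fatty acid carrier, 0.284 and 1.07 times. Of 5 adipocyte genes, 3 were lower in both Ezh2cKO arrays and 0 higher, with medians of -1.81 and -0.20 within the numbers and of -1.15 for WT replicate 2 minus WT replicate 1. Cdh5, a cadherin of endothelial cells, was 0.425 and 1.03 times its WT level, and Kdr, a receptor of vascular endothelial growth factor, 0.437 and 1.06 times. These Cdh5 values are from its brightest probe set (log2 -0.60), while its other kept probe set had a log2 difference of 0.06. Of 10 endothelial genes, 0 were separated in either direction (medians -0.87 and 0.09). Both lists passed camera downwards (adipocyte mean -1.48, adjusted p = 7.40e-09, and endothelial mean -0.39, adjusted p = 1.04e-04), with adjusted p = 0.593 and 0.619 with an estimated correlation. Camera at the preset correlation also called both in the crossed split, which does not follow genotype. There the adipocyte mean was -1.18 (camera adjusted p 6.88e-07) and the endothelial mean -0.49 (7.65e-09), so these calls are not particular to genotype. Without Ezh2cKO replicate 1 the endothelial mean was 0.19 (adjusted p 0.105), so the direction turned, and without Ezh2cKO replicate 2 it was -0.96. The adipocyte mean was -0.76 without WT replicate 1 and -1.01 without Ezh2cKO replicate 1. In limma on all 4 arrays the adjusted p was 0.999979 for each of Car3, Adipoq and Fabp4. With 1 array left out the log2 differences ranged from -4.00 to -1.92 for Car3, -3.97 to -0.99 for Adipoq (nearest 0 without WT replicate 1) and -1.51 to -0.21 for Fabp4 (nearest 0 without Ezh2cKO replicate 1).

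Transcripts of dermal fibroblasts were abundant on all 4 arrays. Dcn, encoding the matrix proteoglycan decorin, had 14352 ± 1522 in WT and 16119 ± 1543 in Ezh2cKO, Postn, the matrix protein periostin, had 14127 ± 336 and 15535 ± 1698, and Col1a1, a chain of type I collagen, had 8087 ± 1475 and 7379 ± 3113. At signals as high as those of Dcn and Postn, differences may be compressed. Of 14 fibroblast genes, 0 were separated in either direction and the list did not pass camera (medians -0.13 and 0.03, adjusted p = 0.81), although its mean was -0.32 without WT replicate 1 (adjusted p 6.64e-05), -0.39 without Ezh2cKO replicate 2 (3.60e-05) and 0.25 without Ezh2cKO replicate 1 (0.00251). No call was made for melanocyte (adjusted p = 0.268), Merkel cell (0.908), periderm (0.0851), immune (0.908), skeletal muscle (0.0654), erythroid (0.908) or Schwann cell and nerve markers (0.302). Skeletal muscle passed with a common median (0.0329), without the intensity trend (0.00605) and with the mean of each gene's probe sets (0.0194), and periderm passed without WT replicate 1 (0.0118) or Ezh2cKO replicate 2 (0.0125). The interferon response (adjusted p = 0.81) and imprinted genes (0.97) did not pass either. Without Ezh2cKO replicate 1 they had means of 0.34 (adjusted p 0.0313) and 0.23 (0.00247), and the imprinted list had -0.19 (0.00719) without WT replicate 1 and -0.25 (0.00371) without Ezh2cKO replicate 2. With 8 of the 28 lists past the threshold at the preset correlation, 0 passed with an estimated correlation and 0 passed fry, where 1 list, the late one, had an unadjusted p under 0.05 in each. The crossed split of the arrays gave 8 lists as well. Of the genes in the 28 lists, 1, Ezh2, passed limma adjusted over the list alone and 0 passed over all genes.

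The makeup of the samples by embryo sex differed between arrays. Xist, the RNA of the inactive X chromosome, was low only in Ezh2cKO replicate 1, at 86.9 against 8669 in WT replicate 1, 10527 in WT replicate 2 and 11333 in Ezh2cKO replicate 2. Y-linked Eif2s3y had a signal of 222 in WT replicate 1, 861 in Ezh2cKO replicate 1, 535 in WT replicate 2 and 404 in Ezh2cKO replicate 2, so 3 of the 4 arrays held Xist together with Y-linked signal. The sex list did not pass camera (adjusted p = 0.163), its mean (-0.28) and median (0.61) differed in sign, and its mean was -0.74 without WT replicate 1 (adjusted p 4.11e-08) and -0.78 without Ezh2cKO replicate 2 (1.35e-09). Mean and median or the direction given by camera or fry also differed in sign for the Hox, barrier lipid, developmental regulator, basal, Merkel cell, proliferation, imprinted, immune and erythroid lists, all of which failed the threshold.

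**Figure D2:**
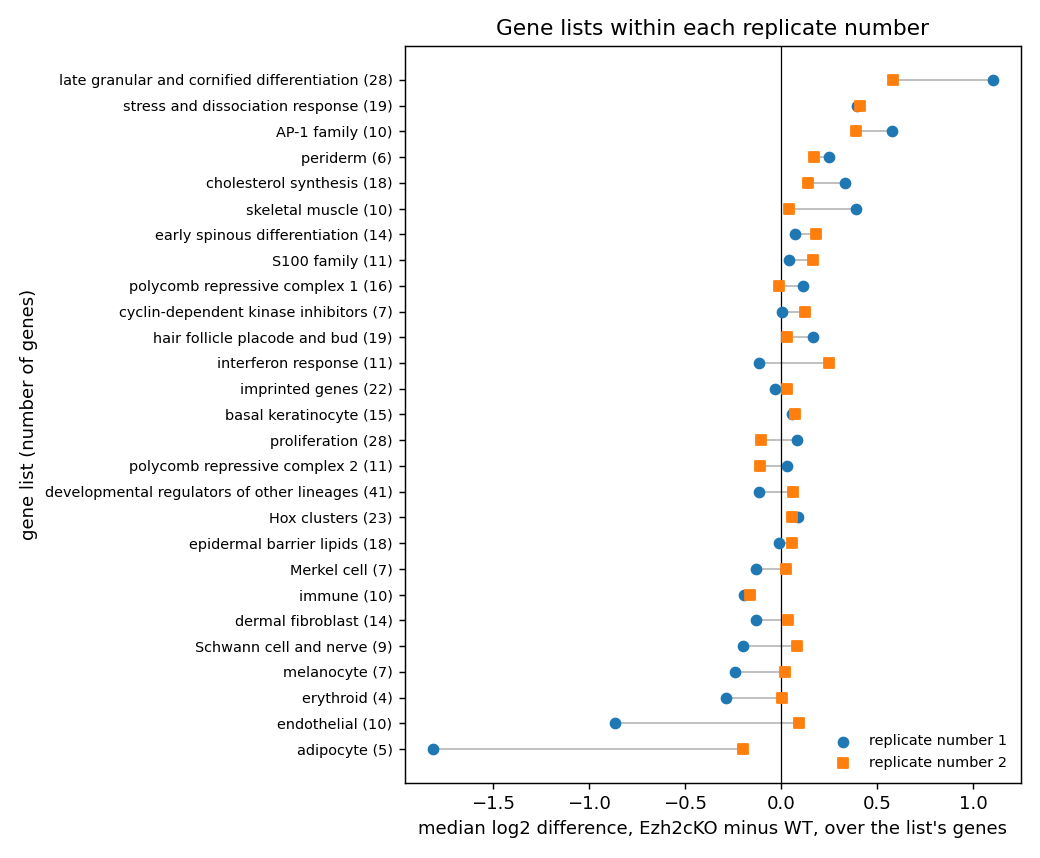
Median log2 difference between Ezh2cKO and WT over the genes of each list (number of genes in parentheses), within the arrays numbered 1 (circles) and within those numbered 2 (squares), without the sex list. The late differentiation list lies farthest to the right within both numbers (1.10 and 0.58), and the adipocyte and endothelial lists lie farthest to the left within number 1 (-1.81 and -0.87).

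Across the whole array, 13 probe sets for 12 genes were at least 2-fold higher in all 4 pairs of an Ezh2cKO and a WT array, and 1, that of Ezh2, was at least 2-fold lower. Zap70, a kinase of T-cell receptor signalling, had 71.2 ± 23 in WT and 401 ± 219 in Ezh2cKO (log2 2.18, SE 0.49), 3.71-fold and 5.53-fold within the numbers. Sfmbt2, an imprinted Polycomb-group gene, had 129 ± 41.7 and 375 ± 13.7 (log2 1.46, SE 0.33). Nts, which encodes the peptide neurotensin, had 96.4 ± 0.706 and 287 ± 81.5 (log2 1.40, SE 0.36). With Flg, Lce1c and Lce1a2 these were the 6 genes whose brightest probe set met the size rule with an unadjusted p under 0.01, and none passed the adjusted threshold. The rest, named after their values were seen, were Lce1d, Mt1, Ccn1, Dusp9, Cgas and 2310050C09Rik, of which Mt1, Ccn1 and Cgas met this rule only with a dimmer probe set. In Mt1, a metal-binding metallothionein, this dimmer probe set had 188 ± 114 in WT and 898 ± 391 in Ezh2cKO (log2 2.22, SE 0.51), while the brightest had 6646 and 7934 (log2 0.25). The brightest probe sets of Ccn1, Cgas and Dusp9 had log2 differences of 0.77, 1.13 and 0.26. In limma 0 probe sets were called higher and 0 lower (lowest adjusted p 0.999979), and 110 had an unadjusted p under 0.05, 94 higher and 16 lower, where 1351 would be expected by chance. In the same fit the split by array number called 8326 probe sets and the crossed split 0, and 4 probe sets differed 2-fold in all pairs of the crossed split. The fit of the genotypes had no block and kept the difference between array numbers in its residual spread. In simulated data with that difference, such a fit recovered 0% of 2-fold, 0% of 4-fold and 49.5% of 8-fold changes. Without WT replicate 1, WT replicate 2, Ezh2cKO replicate 1 and Ezh2cKO replicate 2, limma called 1, 42, 0 and 8 higher and 1, 10, 0 and 19 lower. Without WT replicate 2 these included Zap70 (adjusted p 0.0261), Mt1 (3.78e-06) and Ccn1 (0.00514, and 0.0446 without Ezh2cKO replicate 2). With 1 array left out the log2 differences ranged from 1.62 to 2.74 for Zap70, 1.61 to 2.82 for Mt1 and 1.40 to 1.95 for Ccn1. The 2-fold counts, with fewer pairs to meet, were then 62, 171, 78 and 70 higher and 12, 20, 31 and 235 lower.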

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

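The alternatives without genes of the sex chromosomes, without the Lce genes, without cross-detecting probe sets, and with the replicate block together with an estimated correlation were chosen after seeing the data, the others before. The causes of the differences below were not tested unless one is named.

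With the replicate block, limma called 5 probe sets higher (Mt1 with its dimmer probe set, Lce1h, Cxcl1, Lce1c and Zap70, of which Lce1h and Cxcl1 were named after their values were seen) and 1 lower, Ezh2 (log2 -1.88, adjusted p 0.0440), with 13 at an adjusted p under 0.1. This blocked fit had 1353 probe sets at an unadjusted p under 0.05, where 1351 would be expected by chance. The labels do not say that a number marks a shared litter, batch or day, so what same-numbered samples share is not known. In simulated data where the numbers did pair the samples, the blocked fit recovered 61.5%, 86.5% and 99.5% of 2-, 4- and 8-fold changes and called 27, 13 and 14 unchanged probe sets. Deviations of same-numbered arrays from their group means correlated at 0.77 across probe sets, and the first principal component (80.8%) separated the numbers. The blocked list calls gained hair follicle (adjusted p 0.0283) and periderm (0.0283), and the late list's mean stayed at 0.99, with adjusted p 0.695 with an estimated correlation, where 0 other lists were called.

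The late list kept its direction and its camera call in all 13 alternatives that used camera at the preset correlation, with means from 0.73 to 1.26, and at 0.63 without the Lce genes and 0.90 without cross-detecting probe sets, where periderm was also called (0.00721). Its mean of 0.99 had an adjusted p of 0.502 with an estimated correlation and 0.739 in fry, and by either of these 0 other lists were called, against 7. Of the other lists, 4 were called without the filter and between 4 and 12 with 1 array left out. The adipocyte call held in 13 of 13 alternatives, the endothelial one in 12, stress and cholesterol in 11 each, AP-1 in 9, and spinous and complex 1 in 8 each.

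The limma counts stayed at 0 except with the block and with arrays left out, where they ranged from 0 to 42 higher and from 0 to 19 lower. The 2-fold count of 13 higher became 59 at 1.5-fold, 5 with a pseudocount of 64, 39 without the filter, 8 with a common median, 12 without genes of the X and Y chromosomes and 62 to 171 with 1 array left out. The count of 1 lower became 10 at 1.5-fold, 17 without the filter, 2 with a common median and 12 to 235 with 1 array left out, where fewer pairs had to meet the rule. The Ezh2 difference ranged from -2.36 to -1.40 with 1 array left out.

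Single genes were run under the alternatives if the naming rule took them by size or from some of the lists. Some genes named after their values were seen were also run. Members taken only from the other lists were not run. The genes run include members whose values the text does not give, such as Dst, Cbx8 and Fos. Of the 66 genes run other than Ezh2, 8 turned direction, each with an array left out. They were Rnf2 (-0.042 to 0.65), Col6a1 (-1.10 to 0.36), Col1a1 (-0.63 to 0.26), Cdh5 (-1.32 to 0.13), Kdr (-1.27 to 0.16), Plvap (-0.72 to 0.066), Esam (-0.95 to 0.15) and Krt10 (-0.070 to 0.22). Over all alternatives, 752 values of the 66 genes kept their direction and side of the threshold, 21 passed it only under an alternative and 10 reversed. Dim genes carry the least certain values, since no background level was used.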

Other observations

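The tests of the late differentiation, endothelial and adipocyte lists, and those of the same-numbered arrays that rest on stress genes and fibroblast markers, were chosen only after the results were seen. The bootstrap intervals below resample the genes of a list as if they were independent. They measure no spread between samples. Fibroblast markers were limited to those below a signal of 5000 as a guard against saturation.

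Genes with higher signal in Ezh2cKO lay next to each other in and beside the epidermal differentiation complex. Over 12501 windows of 8 neighbouring measured genes, 20 had a mean log2 difference above 0.60, the 95th percentile of the highest window of 1000 shuffled gene orders, and 0 lay below the lower threshold. These 20 are, or overlap, the 3 separate windows named below, so they mark 1 region and not a pattern across the genome. Without probe sets that can detect paralogs, 15 overlapping windows exceeded their threshold. The highest window, with a mean of 1.91 (2.49 within number 1 and 1.34 within number 2, permutation p = 0.000999, the smallest that 1000 shuffles can give), held Lce1a2, Lce1c, Lce1d, Lce1f, Lce1h, Lce1i, Kprp and 2310050C09Rik, and the next separate windows held Lce3f, Crct1, Lce1m, Flg, Hrnr, Tchh, S100a10 and Them4 (0.91) and S100a9, Lor, Sprr2k, Sprr1b, Sprr1a, Ivl, Lce1a1 and Lce1b (0.68). Without probe sets that can detect paralogs, the third separate window was another one, with a mean of 0.52, and did not exceed the threshold. The 3 windows named lie in or beside the epidermal differentiation complex, which the late list also draws on, so the windows are not independent of that list, and their genes are named after their values were seen.

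The late differentiation list was higher in Ezh2cKO, and 3 technical explanations were weighed. A different mix of embryo sexes in Ezh2cKO replicate 1 would leave number 2 unchanged, but there the list median was 0.58 (95% bootstrap interval 0.20 to 0.97), with 25 of 28 genes higher. Paralogous probes of the Lce genes would leave the other members near 0, but their mean was 0.63 (0.33 to 0.97, n = 17). For these arrays, the values argue against each of these as the whole cause. Those within number 2 rest on 1 array per genotype. More granular-layer cells in the Ezh2cKO fractions stay open. The sort was for basal cells, but the spinous keratin Krt1 had a mean signal of 11727 in WT. For that layer's enzymes, 15 genes had a median of 0.28 (95% bootstrap interval 0.06 to 0.44) against 1.83 for 13 structural genes. The enzyme genes had a higher median WT signal (221 against 171), and a higher starting level can hide a small share of cells. Signals of different probe sets are not directly comparable as levels, so this comparison decides nothing. The dissociation response and the genotype itself stay open, untested.

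Endothelial genes were lower in Ezh2cKO replicate 1 than in WT replicate 1, as were adipocyte genes, for which WT replicate 1 also stood apart from WT replicate 2 (median -1.15 for replicate 2 minus replicate 1). Fewer non-keratinocyte cells of every kind would lower fibroblast markers too, but those below a signal of 5000 had a median of -0.15 within number 1 (95% bootstrap interval -0.29 to 0.08, n = 9), above the endothelial -0.87 (upper limit -0.60). An effect of Ezh2 loss in both replicates would lower the endothelial list within number 2, but its median there was 0.094 (0.04 to 0.16). For the 5 adipocyte genes the median within number 2 was -0.20 (-0.94 to 0.10), so for them an effect of Ezh2 loss and a difference of WT replicate 1, Ezh2cKO replicate 1 or both cannot be told apart. Carry-over of vessel and fat cells that differed between samples stays open. The sort was for basal cells, but in WT replicate 1 the most abundant adipocyte markers, Fabp4 and Car3, had signals of 8883 and 7438.

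Arrays with the same number resembled each other more than arrays of the same genotype (1902 against 14 probe sets 2-fold apart), and the design names no biological difference between the numbers, so only technical explanations, cell content and handling included, were weighed. A difference at the low end of the MAS5 scale may account for part: quantile normalization took the count among dim probe sets (mean signal under 1000) from 1827 to 839, against 8 between genotypes, but among 7430 bright probe sets 75 differed without this normalization, against 1. More dermal fibroblasts in the arrays numbered 2 stay open, as markers below 5000 were higher by a median of 0.79 in WT (95% bootstrap interval 0.40 to 0.97) and 0.85 in Ezh2cKO (0.42 to 1.37). A stronger dissociation response stays open too, since leaving out its 55 probe sets (1892 still differed) could not decide it. A batch of preparation or hybridisation, which the labels do not give, stays open, as control probe sets differed with the number: 18S ribosomal RNA had signals of 623 and 446 in the arrays numbered 1 (WT, then Ezh2cKO) against 93.2 and 130.2 in those numbered 2, and the hybridisation control bioC 1211 and 1184 against 761 and 863.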
